A study of Mus musculus with 6 samples.

How the data were processed

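RNA was extracted with Trizol from bone marrow B cells of C57BL/6 mice, isolated with a magnetic kit for mouse B cells, and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The table deposited by the authors holds raw read counts per gene for 6 libraries, with no normalization and no pooled column. Reads were aligned with HISAT2 to mm10, per the submitters' processing notes. The aligner's version, the counting tool, its strand setting and the annotation were not given in the sources used here, so reads of overlapping genes on opposite strands and of near-identical copies cannot be told apart. Of 55487 gene rows 55141 matched a symbol and position in the GENCODE annotation of the same build, and 346 rows without a symbol took 0.0368% of counts. All columns mapped to a sample by name. Total counts ran from 13546781 to 20244412 per library.

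Libraries were grouped by genotype in the labels into 3 controls (floxed Slc7a5, no Cre) and 3 knockouts (the same with Cre at the Cd19 locus). The main test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes were kept by edgeR filterByExpr with the group and its default minimum of 10 counts, which left 14765, and scaled by TMM. The edgeR 4.0.16 quasi-likelihood test in R 4.3.3 compared the groups with a two-sided test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested with a threshold of 0.05. The common dispersion was 0.0555. Levels are CPM on TMM-scaled library sizes. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic and intervals are 95%.

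Gene lists numbered 43 with 1139 memberships, of which 1135 matched a gene row, and 42 lists had at least 5 tested members. They were the lists named in the results, covering amino acid and other metabolic pathways, cell cycle, stress, B cell stages, other marrow cell types and RNA quality. Each list was tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 42 lists, and again with an estimated correlation and with fry, which does not compare a list with other genes. Counts adjusted over the list alone use the edgeR p-values of its members. Some genes are in several lists, such as 12 of the 20 pro-B genes and 10 of the 17 small pre-B genes. The named genes were Slc7a5, Slc3a2 and Cd19, then the genes with the largest changes among those passing, or, since none passed, the 5 with the smallest p in each direction, and up to 4 members with the smallest p of each list. Immunoglobulin and T cell receptor segments and gene models without a proper name were passed over in the second group, which skipped 0 higher and 1 lower gene.

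The fit was tested on simulated data for 14512 genes with the libraries' means and sizes. It recovered 28 of 97 genes changed by 2-fold (28.9%) and 79 of 98 changed by 4-fold (80.6%), with 14 unchanged genes among 136 calls. It called the 1 list with an added shift and 0 others. Genes were drawn independently of each other in the simulation. Neither the recovery nor the list result carries over to the real counts, where the estimated correlation within lists reached 0.976. There, other splits of the libraries into groups of 3 gave 8 to 23 lists past the threshold. Single values were compared by two-sided exact permutation tests, whose smallest p is 0.1 for 3 libraries against 3. No pair of libraries matched within sampling noise. Positions of small p-values were scanned in windows of 5 Mb and compared with 10000 random reassignments of p-values to gene positions.

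Alternatives were other scalings, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 50 counts in at least 3 libraries, removal of immunoglobulin, haemoglobin and mitochondrial genes, the replicate number as a block, a minimum fold change of 2, and leaving out each library in turn. After the data had been seen, 3 more were added: the mean of the erythroid list as a covariate, voom with library quality weights, and leaving out controls 1 and 2.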

Results

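RNA sequencing counts were available for B cells of mouse bone marrow from 2 genotypes, with 3 libraries of each. Control libraries came from C57BL/6 mice whose Slc7a5 alleles carry loxP sites and which have no Cre recombinase in their labelled genotype. Knockout libraries came from mice that also carry Cre at the Cd19 locus, which removes the floxed part of Slc7a5 in cells of the B lineage. The groups therefore differ in Cre and in the Cd19 insertion too, and effects of these cannot be told apart from those of Slc7a5 loss. Slc7a5 encodes LAT1, the light chain of a transporter that carries large neutral amino acids such as leucine into cells. Total counts per library were 16984224, 16227439 and 17466656 in controls 1, 2 and 3 and 13546781, 20244412 and 20116131 in knockouts 1, 2 and 3, a range of 1.49-fold. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. The comparison asks which transcripts differ between marrow B cells of these genotypes.

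The targeted gene had lower CPM in all 3 knockout libraries than in any control library. Slc7a5 (ENSMUSG00000040010, chromosome 8, 121881150 to 121907694, mm10, protein-coding) stood at 85.0 ± 32.0 CPM in controls (SD, n = 3) and 45.4 ± 9.70 CPM in knockouts (SD, n = 3), a log2 fold change of -0.90 with a standard error of 0.29 and a 95% interval from -1.60 to -0.20. The libraries held 81.2, 119 and 55.1 CPM in controls 1, 2 and 3 and 34.3, 49.8 and 52.2 CPM in knockouts 1, 2 and 3. The edgeR quasi-likelihood test gave an unadjusted p of 0.0186 and a Benjamini-Hochberg adjusted p of 0.851 over 14765 genes. The two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. The order of the controls, with control 2 highest and control 3 lowest, was that of the erythroid list of red cell genes. The log2 fold change was -1.13 without control 3 (edgeR adjusted p = 0.0166), -0.59 without control 2, -0.39 with the erythroid list mean as a covariate and -0.27 without controls 1 and 2 (edgeR adjusted p = 0.758). The count covers the whole gene, including exons outside the floxed part, so it does not measure how many cells had lost the transporter. Slc3a2, the heavy chain that pairs with LAT1 at the membrane (chromosome 19, 8706882 to 8723369), stood at 144 ± 17.2 and 131 ± 7.96 CPM (SD, n = 3 each), a log2 fold change of -0.13 with a standard error of 0.12 and an edgeR adjusted p of 0.855. Cd19, the B cell surface gene at which Cre was inserted (chromosome 7, 126408450 to 126414889), varied widely, with 534 ± 427 CPM in controls and 617 ± 257 CPM in knockouts (SD, n = 3 each) and an edgeR adjusted p of 0.943. Relative to Cd79a, another B cell gene, Cd19 was at 0.751 ± 0.157 in controls and 0.752 ± 0.214 in knockouts (SD, n = 3 each; two-sided exact permutation p = 1).

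**Figure D1:**
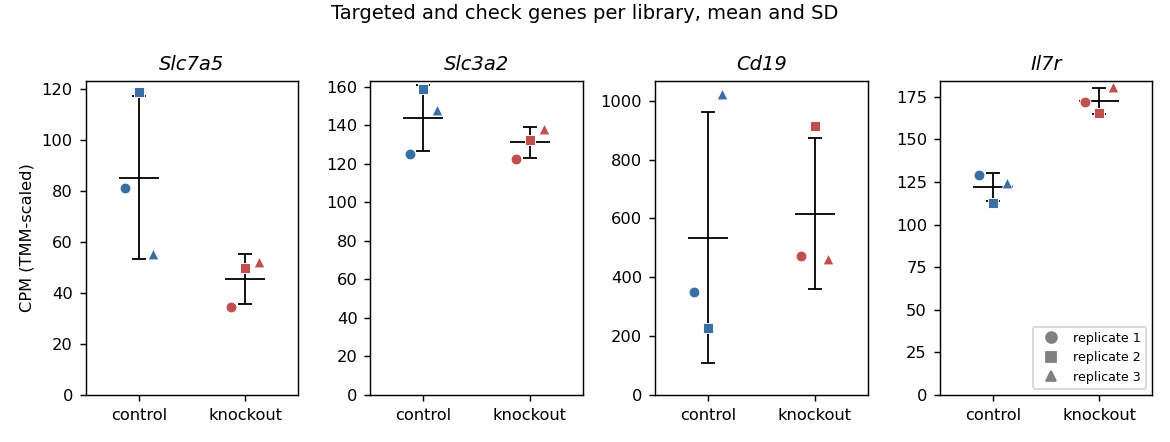
CPM (TMM-scaled) of Slc7a5, Slc3a2, Cd19 and Il7r in each library, with controls in blue, knockouts in red, marker shapes for replicates 1 to 3, and black bars for the mean and SD (n = 3). All 3 knockout libraries lie below all 3 controls for Slc7a5 (34.3 to 52.2 against 55.1 to 119 CPM), while the groups overlap for Slc3a2 and Cd19.

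Across all genes, no transcript passed the threshold in the edgeR test, and the genes with the smallest p lay mostly in 1 stretch of chromosome 8. Eno1b, an enolase gene, stood at 8.17 ± 1.62 CPM in controls and 46.6 ± 16.2 CPM in knockouts (SD, n = 3 each), a log2 fold change of 2.51 with a standard error of 0.28. Ifi30, a lysosomal thiol reductase used in antigen processing, stood at 213 ± 48.0 and 564 ± 50.9 CPM (log2 fold change 1.40, standard error 0.18). Lpar2, a receptor for lysophosphatidic acid, stood at 15.2 ± 3.10 and 4.68 ± 0.0982 CPM (log2 fold change -1.70, standard error 0.19). Pde4c, a cyclic AMP phosphodiesterase, stood at 5.85 to 19.5 CPM in control libraries and 57.5 to 88.3 CPM in knockout libraries (log2 fold change 2.44, standard error 0.41).

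Of the 10 genes with the smallest p, 5 per direction, 7 lay between 69610857 and 70766663 of chromosome 8. On the higher side these were Zfp868 (69610857 to 69625548, log2 fold change 1.16), Zfp964 (69654479 to 69666982, 2.04), Pde4c (70723720 to 70751186) and Ifi30 (70762774 to 70766663). On the lower side they were Zfp866 (69761326 to 69791178, log2 fold change -0.78), Lpar2 (69822429 to 69831102) and Pbx4 (69832491 to 69872292, -2.25). The remaining 3 were Eno1b on chromosome 18 (48045335 to 48048412), Tyro3 on chromosome 2 (119797733 to 119818104, log2 fold change -3.12, below 1 CPM in both groups) and Pdgfb on chromosome 15 (79995874 to 80014977, -1.71). All 10 had no overlap between the 3 values of each group. Zfp868, Zfp964 and Zfp866 belong to a family of similar zinc finger genes, and Eno1b resembles Eno1, so reads may have been shared between copies in the counting.

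The number of genes past an edgeR adjusted p of 0.05 was 0, with 716 genes at an unadjusted p under 0.05, 242 higher and 474 lower in knockouts, against 738.25 that chance alone would give among 14765 tests. The smallest edgeR adjusted p was 0.370, shared by Eno1b, Lpar2 and Zfp866. DESeq2 called 26 genes, 13 in each direction, of which 11 lay in the chromosome 8 stretch, and limma-voom called 0 with 540 at an unadjusted p under 0.05. Without control 3, edgeR called 1767 genes, 649 higher and 1118 lower. The lower ones included 19 of 20 erythroid, 18 of 22 neutrophil, 13 of 15 T cell, 13 of 18 natural killer and 32 of 42 mitosis genes. In each of these lists controls 1 and 2 lay above every knockout. The higher ones included 22 of 33 genes of mature B cells, a list in which controls 1 and 2 lay below every knockout. The groups did not overlap for 9.01% of tested genes, where chance gives 10%.

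**Figure D2:**
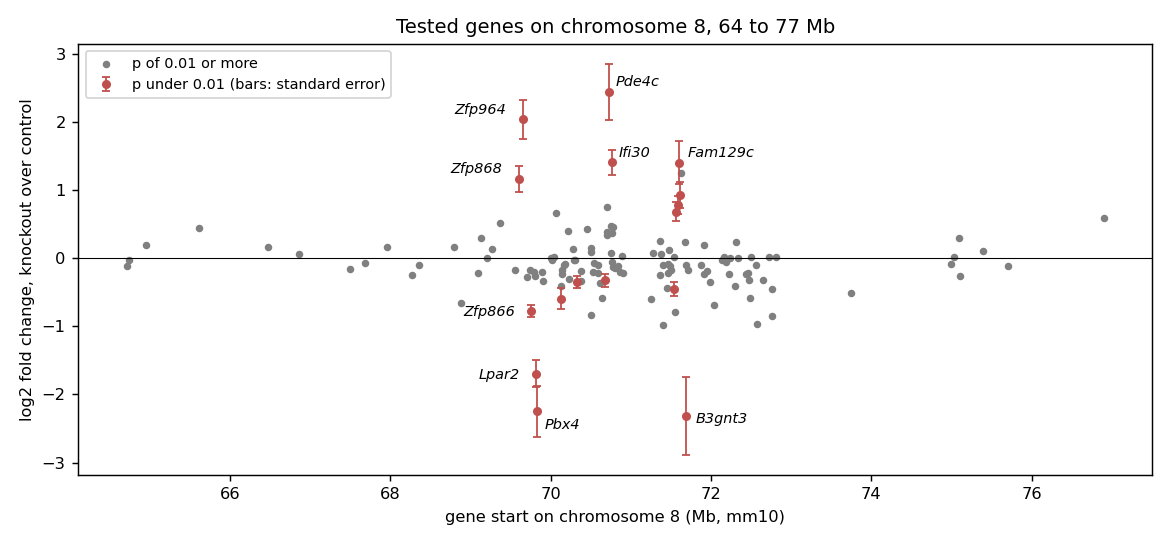
Log2 fold change (knockout over control) of each tested gene against its start on chromosome 8 in Mb (mm10). Grey points are genes at an unadjusted edgeR p of 0.01 or more, and red points with standard error bars are genes under 0.01, 8 higher and 8 lower, which lie between 69610857 and 71701789.

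Marker lists of several other blood cell types lay lower in the knockout group and were, with both cell cycle lists, among those with the smallest p. Erythroid genes had a median log2 fold change of -2.19, T cell genes -2.32, natural killer and innate lymphoid genes -1.56 and neutrophil genes -1.01. In each of these 4 lists controls 1 and 2 lay above all 3 knockouts. Control 3 lay below all 3 knockouts for the erythroid and neutrophil lists, among them for the T cell list, and level with the highest of them for the natural killer list. Of the 42 lists with at least 5 tested members, limma camera with a preset correlation of 0.01 placed 21 past an adjusted p of 0.05, 9 higher and 12 lower. With an estimated correlation 0 of the 42 passed (lowest limma camera adjusted p = 0.736), and fry passed 0.

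Haemoglobin genes, the oxygen carriers of red cells, took 1.35%, 4.16% and 0.0761% of counts in controls 1, 2 and 3 and 0.113%, 0.0830% and 0.154% in knockouts 1, 2 and 3 (two-sided exact permutation p = 0.4). Of 20 erythroid genes 19 had a negative fold change (limma camera adjusted p = 5.94e-14, adjusted p = 0.736 with an estimated correlation), and 0 passed when adjusted over the list alone. Hbb-bs held 7992, 28683 and 444 CPM in controls 1, 2 and 3 and 652, 485 and 898 CPM in knockouts 1, 2 and 3, and Alas2, the first enzyme of haem synthesis in red cells, had a log2 fold change of -3.92 with a standard error of 1.23. All 15 tested T cell genes were negative, 9 of them passing when adjusted over the list alone and 0 over all genes in edgeR (limma camera adjusted p = 1.23e-12, adjusted p = 0.736 with an estimated correlation). DESeq2 called the list member Trbc1, a constant region of the T cell receptor, over all genes (adjusted p = 0.0494), and Cd3e, a list member that the edgeR filter left out (0.0148). Cd3d, a subunit of the T cell receptor complex, had 6.85 ± 7.23 CPM in controls and 0.796 ± 0.0682 CPM in knockouts (SD, n = 3 each). All 18 natural killer and innate lymphoid genes were negative, with 9 passing when adjusted over the list alone and 0 over all genes in edgeR (limma camera adjusted p = 6.34e-19, adjusted p = 0.736 with an estimated correlation). Eomes, a transcription factor of natural killer cells, had a log2 fold change of -2.24 (standard error 0.56; DESeq2 adjusted p = 0.0177 over all genes), and Il2rb -2.01 (0.58). Of 22 neutrophil genes 21 were negative (limma camera adjusted p = 3.56e-05, adjusted p = 0.741 with an estimated correlation), with 0 passing when adjusted over the list alone. Without controls 1 and 2 the medians of the neutrophil and erythroid lists were 1.05 and 0.63. The neutrophil list did not pass without control 2 (median -0.34, limma camera adjusted p = 0.540). The granule genes Camp and Ltf had log2 fold changes of -1.34 (standard error 0.67) and -1.33 (0.72).

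Megakaryocyte and platelet genes had a median log2 fold change of -0.71, with 13 of 14 negative (limma camera adjusted p = 2.38e-10, adjusted p = 0.736 with an estimated correlation), 5 passing when adjusted over the list alone and 0 over all genes in edgeR. Controls 1 and 2 lay 0.60 and 0.62 above the mean of this list and control 3 at -0.31, level with the knockouts. Without controls 1 and 2 the test pointed the other way (median -0.0472). Mpl, the thrombopoietin receptor, was at 3.50 ± 0.204 CPM in controls and 1.84 ± 0.259 CPM in knockouts (SD, n = 3 each). Basophil, eosinophil and mast cell genes had a median of -0.29, with 17 of 19 negative (limma camera adjusted p = 4.3e-06, adjusted p = 0.741 with an estimated correlation) and 1, the mast cell protease Cpa3 (log2 fold change -0.59, standard error 0.12), passing when adjusted over the list alone. Controls 1 and 2 were the highest libraries of that list too (0.30 and 0.50), with control 3 at -0.30 among the knockouts. The median was 0.11 without controls 1 and 2. Stem and progenitor genes had a median of -0.19, with 11 of 15 negative (limma camera adjusted p = 0.0108, adjusted p = 0.736 with an estimated correlation). Monocyte and macrophage genes lay the other way, with a median of 0.20 and 20 of 22 positive (limma camera adjusted p = 2.01e-03, adjusted p = 0.741 with an estimated correlation), Cd14 having a log2 fold change of 0.29 (standard error 0.13). The median of this list was -0.053 with library quality weights. Without control 3 or knockout 1 neither the monocyte list (limma camera adjusted p = 0.540 and 0.391) nor the stem and progenitor list (0.0527 and 0.0619) passed. The medians were then 0.0529 and -0.0062 for the monocyte list and -0.16 and -0.32 for the stem and progenitor list. Dendritic cell genes (median 0.15, 12 of 17 positive) and stroma and endothelium genes (median 0.07, 9 of 15 positive) did not pass, with limma camera adjusted p of 0.311 and 0.338. The dendritic list passed on the higher side without knockout 2 (limma camera adjusted p = 9.74e-04) and the stroma list on the lower side without control 2 (4.32e-03). The single tested sex-linked gene, Xist, was at 1753 ± 136 and 1702 ± 120 CPM (SD, n = 3 each).

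**Figure D3:**
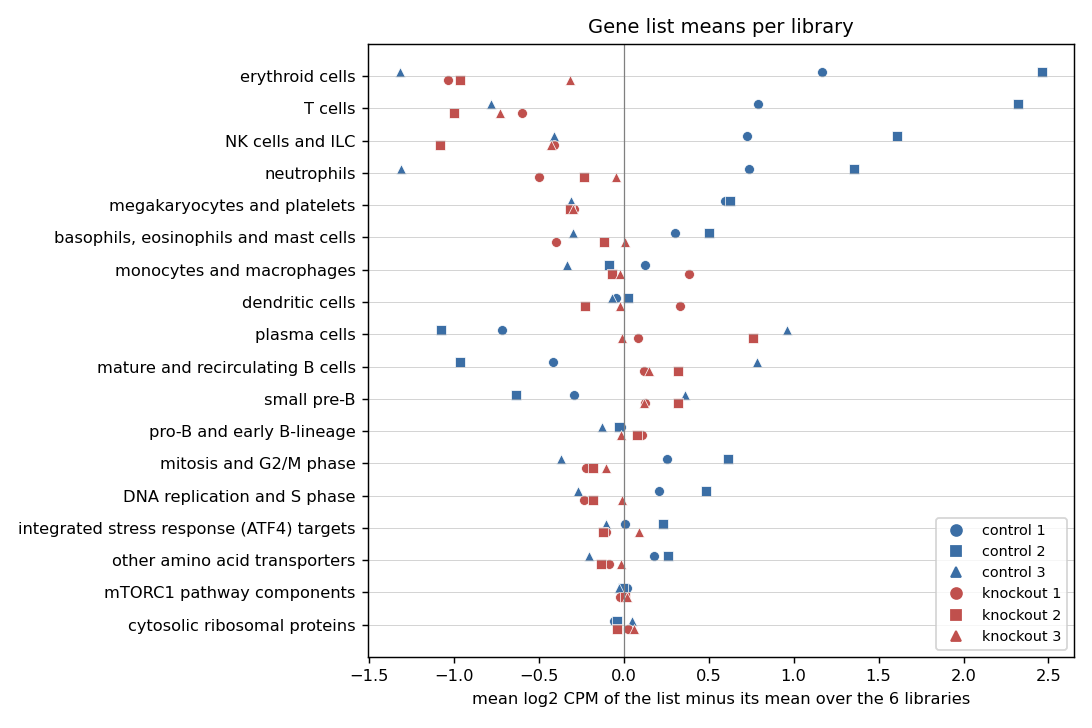
Mean log2 CPM of 18 fixed gene lists in each library minus the mean of that list over the 6 libraries, with controls in blue and knockouts in red and marker shapes for replicates 1 to 3. Control 2 lies at 2.46 and control 1 at 1.17 for the erythroid list, where control 3 lies at -1.32 and the knockouts between -1.04 and -0.32.

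Lists of B cell stages, other than large cycling pre-B and B-1 and marginal zone cells, lay slightly higher in the knockout group. Control 3 had the highest and control 2 the lowest values of the small pre-B and mature lists. Small pre-B genes had a median log2 fold change of 0.31, with 16 of 17 positive (limma camera adjusted p = 3.13e-04, adjusted p = 0.741 with an estimated correlation). Rag1, which cuts DNA for receptor gene rearrangement, was at 441 ± 134 and 599 ± 50.7 CPM (SD, n = 3 each), and Tifa at 316 ± 85.4 and 438 ± 16.4 CPM. Genes of mature and recirculating B cells had a median of 0.19, with 30 of 33 positive (limma camera adjusted p = 9.94e-04, adjusted p = 0.798 with an estimated correlation). Without control 2 the median of that list was -0.14. With the erythroid list mean as a covariate, and without controls 1 and 2, the medians turned negative for the small pre-B list (-0.0516 and -0.21), the mature list (-0.27 and -0.59) and the immature list (-0.0209 and -0.13). Immature and transitional genes had a median of 0.25 (11 of 13 positive, limma camera adjusted p = 0.0166, adjusted p = 0.741 with an estimated correlation). Pro-B and early B-lineage genes had a median of 0.14 (13 of 20 positive, limma camera adjusted p = 0.0212, adjusted p = 0.736 with an estimated correlation). In that list Il7r, the receptor for interleukin 7 on early B cells, passed when adjusted over the list alone and, over all genes, in DESeq2 (adjusted p = 0.0322) but not in edgeR (adjusted p = 0.851), at 122 ± 8.31 CPM in controls and 173 ± 7.72 CPM in knockouts (SD, n = 3 each), a log2 fold change of 0.50 with a standard error of 0.09. Large cycling pre-B genes (median -0.21) and genes of B-1 and marginal zone B cells (median -0.19) did not pass, with limma camera adjusted p of 0.487 and 0.319. Without control 2 the small pre-B and mature lists did not pass (limma camera adjusted p = 0.0753 and 0.793), while the B-1 and marginal zone list passed on the lower side (4.32e-03). The immature list did not pass without control 1, control 2 or knockout 1 (limma camera adjusted p = 0.0972, 0.514 and 0.0503). Its medians were then 0.13, 0.0155 and 0.19. The pro-B list did not pass without control 3 or knockout 1 (limma camera adjusted p = 0.132 and 0.0893), with medians of 0.20 and 0.12.

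Plasma cell genes had a median log2 fold change of 0.19, with 18 of 22 positive (limma camera adjusted p = 2.31e-03, adjusted p = 0.741 with an estimated correlation). Control 3 was the highest library of this list (0.96 above the mean) and knockout 2 the next (0.76), with controls 1 and 2 at -0.72 and -1.08. The median was -0.0308 with the erythroid list mean as a covariate and -0.24 without controls 1 and 2. Igha, the constant region of IgA, was at 17.0 ± 18.8 CPM in controls and 164 ± 119 CPM in knockouts (SD, n = 3 each), a log2 fold change of 3.27 with a standard error of 0.98, and Ighg3 had a log2 fold change of -2.85 with a standard error of 1.70. B cell receptor signalling genes had a median of 0.17, with 25 of 34 positive (limma camera adjusted p = 0.0107, adjusted p = 0.810 with an estimated correlation), and the median was -0.0534 without control 2, -0.16 with the covariate and -0.28 without controls 1 and 2. Transcription factors of the B lineage had a median of 0.21, with 20 of 25 positive (limma camera adjusted p = 0.0108, adjusted p = 0.769 with an estimated correlation). Control 3 was the highest library of that list (0.30 above the mean). The test passed in the other direction with the covariate (median -0.0708, limma camera adjusted p = 0.0395). Without controls 1 and 2, which leaves 1 control library, the median was -0.21. Without control 1 or control 2 none of these 3 lists passed (limma camera adjusted p = 0.0818 and 0.163 for plasma cells, 0.182 and 0.874 for receptor signalling, 0.0703 and 0.619 for transcription factors). Their medians in the same order were 0.0932 and 0.0495, 0.0439 and -0.0534, and 0.117 and 0.0165. Without knockout 2 the receptor signalling list did not pass (limma camera adjusted p = 0.0618), nor the transcription factors without knockout 1 or knockout 2 (0.0504 and 0.0560). Among the transcription factors Zeb2 was at 321 ± 29.2 and 422 ± 12.2 CPM (SD, n = 3 each), a log2 fold change of 0.40 with a standard error of 0.10.

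Lists tied to amino acids did not pass in the main fit, apart from that of serine, one-carbon and nucleotide synthesis. That list shares Phgdh, Psat1 and Mthfd2 with the ATF4 targets (limma camera adjusted p = 7.75e-03, adjusted p = 0.792 with an estimated correlation). Transcript levels of these lists do not measure amino acid supply itself. Targets of ATF4, the transcription factor of the response to amino acid shortage, had a median log2 fold change of -0.06 with 17 of 26 negative (limma camera adjusted p = 0.319). Slc6a9, a glycine transporter, was high in controls 1 and 2 as the erythroid list was, with 122 CPM in control 2 against 9.62 CPM in control 3 and 11.2 to 18.2 CPM in knockouts. Its log2 fold change of -2.15 was -1.18 without control 2, -0.06 with the erythroid list mean as a covariate and 0.52 without controls 1 and 2. Mthfd2, a mitochondrial enzyme of one-carbon metabolism, had a log2 fold change of -0.30 with a standard error of 0.17. Other amino acid transporters had a median of -0.03 (limma camera adjusted p = 0.392), with log2 fold changes of -1.42 for Slc43a1 (standard error 0.53), -0.32 for Slc7a1 (0.12) and 0.30 for Slc36a4 (0.13). Slc43a1 too was high in controls 1 and 2 (105 and 221 CPM, against 44.2 CPM in control 3), with a log2 fold change of -0.21 with the covariate. The cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, had a median of -0.05 (limma camera adjusted p = 0.301), with Aars at -0.29 (standard error 0.13). Genes of branched-chain amino acid breakdown had a median of 0.10 (limma camera adjusted p = 0.297). Components of the mTORC1 pathway, which senses amino acids, had a median of -0.004 and a mean of -0.008 while the test pointed up (limma camera adjusted p = 0.796), and Fnip2 was at 36.8, 59.6 and 17.9 CPM in controls 1, 2 and 3 and 18.9 ± 2.21 CPM in knockouts (SD, n = 3), with a log2 fold change of -0.15 with the covariate. Ribosomal protein genes had a median of 0.04 (limma camera adjusted p = 0.192), and genes of ribosome biogenesis and MYC targets -0.06 (0.144), with Odc1 at -0.49 (standard error 0.28). The ribosomal protein list passed on the higher side without knockout 2 (limma camera adjusted p = 0.0389). The biogenesis list passed on the lower side without knockout 3 (8.81e-04).

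Among cell cycle and metabolic lists, all 42 genes of mitosis and G2/M phase and all 41 of DNA replication and S phase had negative fold changes, with medians of -0.40 and -0.30. Their limma camera adjusted p values were 1.69e-12 and 2.66e-10, and both had an adjusted p = 0.741 with an estimated correlation. As in the erythroid list, control 2 was the highest library for both lists (0.62 and 0.48 above the mean) and control 3 the lowest (-0.37 and -0.27). With the erythroid list mean as a covariate the medians were 0.0465 and 0.0243. Without controls 1 and 2, which leaves 1 control library, both medians were positive too (0.18 and 0.15). Plk1, a mitotic kinase, was at 81.7 ± 24.0 and 54.8 ± 5.20 CPM (SD, n = 3 each), and Uhrf1, a factor that copies DNA methylation, at 261 ± 43.4 and 195 ± 17.2 CPM. Glycolysis genes had a median of -0.13 with 19 of 22 negative (limma camera adjusted p = 3.86e-03, adjusted p = 0.741 with an estimated correlation). This list too was high in controls 2 and 1 (0.30 and 0.16 above the mean) and had control 3 at -0.17, among the knockouts. Its median was 0.0129 with the erythroid list mean as a covariate and 0.0509 without controls 1 and 2. Eno1 had the lowest p of that list, at 209 ± 20.9 and 106 ± 41.3 CPM, and shares sequence with Eno1b. Genes of serine, one-carbon and nucleotide synthesis had a median of -0.16 (23 of 29 negative, limma camera adjusted p = 7.75e-03, adjusted p = 0.792 with an estimated correlation), with Rrm2 at -0.66 (standard error 0.34). It showed the same order of controls (0.21, 0.11 and -0.12 for controls 2, 1 and 3). The test of that list pointed the other way with the covariate (median -0.0303) and without controls 1 and 2 (median 0.0485). It did not pass without control 2, knockout 1 or knockout 2 (limma camera adjusted p = 0.163, 0.176 and 0.0521), nor did glycolysis without control 2 (0.0851).

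Signs of RNA quality were mixed. Mitochondrially encoded transcripts took 1.73% ± 0.0300 of counts in controls and 1.97% ± 0.0831 in knockouts (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). Their list had a median log2 fold change of 0.22 with 11 of 12 positive (limma camera adjusted p = 7.59e-03, adjusted p = 0.736 with an estimated correlation). Heat shock genes had a median of -0.16 with 13 of 15 negative (limma camera adjusted p = 8.02e-03, adjusted p = 0.741 with an estimated correlation), with Hspa1b at -1.23 (standard error 0.59). Immediate early genes had a median of 0.02 (limma camera adjusted p = 0.727), although Egr1 was at 468 ± 107 and 313 ± 31.2 CPM (SD, n = 3 each). Lists of nuclear oxidative phosphorylation genes (median -0.06), the proteasome (-0.05), the unfolded protein response (0.02), NF-kB targets (0.08), cholesterol synthesis (-0.05), the BCL2 family (-0.04) and interferon-stimulated genes (-0.01) did not pass, with limma camera adjusted p of 0.0977, 0.270, 0.319, 0.419, 0.525, 0.796 and 0.796. Autophagy and lysosome genes had a median of 0.05 and a mean of -0.001 (limma camera adjusted p = 0.599), and p53 targets a median of 0.02 and a mean of -0.009 (0.799), with the test pointing up for both. Without control 3 the mitochondrial and heat shock lists did not pass (limma camera adjusted p = 0.101 and 0.370), although their medians stayed near those of the main fit (0.24 and -0.14). The former did not pass without knockout 2 (median 0.14, limma camera adjusted p = 0.0583), nor the latter without knockout 1 (median -0.12, limma camera adjusted p = 0.124). On the higher side the immediate early list passed without control 3 or knockout 1 (limma camera adjusted p = 3.39e-03 and 0.0429) and the NF-kB list without control 3 (1.47e-04). On the lower side the oxidative phosphorylation list passed without control 3 or knockout 1 (limma camera adjusted p = 0.0471 and 0.0223). The interferon list passed as lower without knockout 1 and as higher without knockout 2 (limma camera adjusted p = 0.0162 and 0.0386).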

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

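The erythroid covariate, the library quality weights and the omission of controls 1 and 2 were chosen after seeing the data. That omission leaves 1 control, which is assumed to vary like the knockouts. A minimum fold change of 2 was applied to the genes passing in the main fit, which were 0, so it could give only 0. The edgeR count of 0 genes held with each scaling, the stricter filter and the removal of immunoglobulin, haemoglobin and mitochondrial genes. Limma-voom also gave 0 (540 genes at an unadjusted p under 0.05, against 716 in edgeR). The count was 26 with DESeq2 (13 higher, 13 lower) and 1 without a filter (Eno1b, higher). Leaving out single libraries gave 0 to 1767 genes, 0 to 649 higher and 0 to 1118 lower: 1767 came without control 3, and 2 without control 2 (Gm12191 and Rpl30-ps1). The count was 8 with the erythroid covariate (4 higher, 4 lower), 999 with quality weights (586 higher, 413 lower) and 82 without controls 1 and 2 (41 higher, 41 lower); the cause was not tested. Lists past the threshold numbered 21, and 0 with an estimated correlation. DESeq2 gave no list result. The log2 fold change of Slc7a5 ran from -1.13 to -0.59 over single libraries left out, and it passed without control 3 and with quality weights (-0.80). It was -0.39 with the erythroid covariate and -0.27 without controls 1 and 2.

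Without controls 1 and 2 these medians or log2 fold changes turned to the other side by the test's direction: Camp 1.00, Ltf 1.29, glycolysis 0.0509, serine and nucleotide synthesis 0.0485, S phase 0.15, mitosis 0.18, interferon-stimulated genes 0.24, immediate early genes -0.27, NF-kB targets -0.28, small pre-B -0.21, mature B -0.59, immature B -0.13, plasma cells -0.24, receptor signalling -0.28, B-lineage factors -0.21, neutrophils 1.05, erythroid 0.63, megakaryocytes -0.0472 (median still negative), basophils 0.11 and stroma -0.26. With the erythroid covariate these did: glycolysis 0.0129, serine and nucleotide synthesis -0.0303 (median still negative), S phase 0.0243, mitosis 0.0465, immediate early genes -0.0865, NF-kB targets -0.12, small pre-B -0.0516, mature B -0.27, immature B -0.0209, plasma cells -0.0308, receptor signalling -0.16, B-lineage factors -0.0708, neutrophils 0.54, erythroid 0.0284 (its own covariate) and stroma -0.17. With quality weights the monocyte list did (-0.053). Over single libraries left out, interferon-stimulated genes ran from -0.15 to 0.0859, mature B from -0.14 to 0.95, receptor signalling from -0.0534 to 0.46 and stroma from -0.22 to 0.25; the cause was not tested. Of the other values for 169 genes and 42 lists, 3443 kept their direction and side of the threshold or stayed uncalled (120 of these changed sign), 58 lost a call and 216 gained one.

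The replicate numbers did not pair the libraries. Taken as deviations from their group's mean, same-numbered libraries correlated at 0.126, -0.239 and -0.224. Controls 2 and 3 correlated best with knockouts 3 and 2. Log2 CPM of the same-numbered pairs correlated at 0.977, 0.953 and 0.983. Over all tested genes control 3 was closer to the knockouts than to the other controls. It correlated at 0.980, 0.988 and 0.983 with knockouts 1, 2 and 3, and at 0.966 and 0.938 with controls 1 and 2. With the replicate number as a block edgeR called 0 genes, with 355 at an unadjusted p under 0.05, and 22 lists passed. The simulation recovered 28.9% of 2-fold changes, but it drew genes independently, so this share does not carry over to the real counts.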

Other observations

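Antibody genes varied between libraries of the same group. Jchain, which joins IgA and IgM units, stood at 4.23, 2.79 and 315 CPM in controls 1, 2 and 3 and at 70.3, 243 and 46.2 CPM in knockouts 1, 2 and 3. Ighg2c stood at 0.744, 0.133 and 37.7 CPM in controls and 0.144, 53.5 and 0.247 CPM in knockouts, so that control 3 and knockout 2 stood apart from the rest. Igha differed from these, at 9.90, 2.72 and 38.3 CPM in controls and 294, 60.8 and 138 CPM in knockouts. Jchain and Ighg2c were chosen after their values were seen, and none of the 3 passed the edgeR test. Isg15, Isg20 and Rsad2, the lower genes with the smallest p in the interferon list, were highest in control 2 and next highest in control 1, as was the erythroid list: Rsad2 stood at 161, 564 and 31.7 CPM in controls and 62.7, 35.8 and 57.7 CPM in knockouts.

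All tests below except the splits of the libraries into other groups for counts of genes and lists were chosen after the result was seen, and 4 of them were changed once. The first version of the test on the monocyte list set controls 1 and 2 against control 3, a division taken from the measured values, and was dropped for one that uses each library on its own. The test on a strain segment first used all 99 tested genes of the window (34 without overlap, 34.3%, against 8.84% elsewhere, Fisher exact p = 2.3e-12), and was narrowed because it ran on genes chosen for the pattern. On chromosome 8, a count of genes at a p under 0.01 with the erythroid covariate gave way to fold changes, because the covariate raised that count over all genes from 74 to 289 (in the window from 16 to 24). A comparison of the window with the genes near Slc7a5 gave way to the distance, because the window had been chosen as the fullest.

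Erythroid, T cell, natural killer and neutrophil lists were lower in the knockout group through controls 1 and 2, although the magnetic isolation should remove these cells. A lower B-lineage share that raised every other cell type alike is argued against as the only source of the pattern. Relative to the monocyte and macrophage list, each list ranged over the libraries by at least 2.42 log2 units (standard error over members 0.26). This smallest range, for neutrophils, lay between controls 2 and 3, so it is not a difference between the groups. The standard error takes members as independent and the extreme libraries were picked by their values, so it is too small. RNA of these cell types in control replicates 1 and 2 may explain the pattern, since in 3 of 4 lists both lay above every knockout and control 3 lay below the highest knockout, with Hbb-bs reaching 28683 CPM and S100a9 6088 CPM in control 2 against 898 and 1868 CPM in the highest knockout (both genes chosen after values were seen). The knockout genotype (absence of Slc7a5, or Cre and its insertion at Cd19) was not excluded, but control 3 lay above every knockout in only 1 of 4 lists. That was the natural killer list, where control 3 lay level with the highest knockout at -0.41. With 3 libraries per group these cannot be told apart.

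Of the 74 genes at an edgeR p under 0.01, 16 (21.6%) started in 1 window of 99 tested genes on chromosome 8 (67000001 to 72000000), 8 higher and 8 lower, where 10000 random reassignments to positions gave at most 6 (permutation p = 1e-04, the smallest they can give). Cell composition as the erythroid list tracks it is argued against. With that list as covariate the fullest window was again on chromosome 8 (68000001 to 73000000). It held 25 of 289 genes at a p under 0.01, where reassignments gave at most 12. All 16 genes kept their direction and a median of 0.882 of their log2 fold change (quartiles 0.792 and 1.04). They had been picked in the fit without the covariate, which favours genes that follow this list little. Other differences in composition were not tested. An effect of the Slc7a5 deletion on neighbouring genes is argued against, since the window ends 49.9 Mb away. A chromosome segment of different strain origin in the groups is a candidate explanation that these values cannot decide. Among the 83 window genes at a p of 0.01 or more, 18 (21.7%, 5 higher and 13 lower) had no overlap between groups. Elsewhere the share was 8.49% (Fisher exact p = 1.88e-04), and chance gives 10%. The window was chosen as the fullest, and the 18 include Cyp4f18, Haus8 and Lpl at an edgeR p of 0.0111, 0.0112 and 0.0113. The test thus follows the same clustering past the cut and lends no separate support to a strain origin. Shared regulation of the region would give the same values, the labels give C57BL/6 for every library, and no sequence reads were analysed here, so the origin of the segment stays a hypothesis.

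Eno1b was higher and Eno1 lower in all 3 knockouts than in any control, at 37.1, 65.2 and 37.3 against 9.95, 7.77 and 6.80 CPM for Eno1b and at 131, 58.4 and 129 against 219, 222 and 185 CPM for Eno1. Reads exchanged one for one between the copies are argued against as the whole cause, since their sum differed by -64.3 CPM (standard error 19.3, two-sided exact permutation p = 0.1, the smallest possible). The sum was not tested with the erythroid covariate, so a change in composition beside an exchange stays open. For Eno1b alone, cell composition as the erythroid list tracks it is argued against. With the erythroid covariate the log2 fold change of Eno1b was 2.57 (standard error 0.33). Other differences in composition were not tested. Reads that match both copies and were left out of the counting, or a sequence variant in either copy, may contribute and were not tested. The same holds for the absence of Slc7a5 and the presence of Cre.

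The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split gave 0 genes and the highest of the others 0, so all 10 gave as many. It gave 21 lists against a highest of 23 in the others, and 4 splits gave as many. For the fullest window it gave 16 genes against a highest of 29, and 3 splits gave as many. The 2 other splits with as full a window put controls 1 and 2 with knockout 1 or knockout 3 and had 637 and 698 genes at a p under 0.01, against 74 in the real split. The split that put them with knockout 2 had 46 such genes and a fullest window of 3. What sets these splits apart was not tested. The fullest windows of the splits with knockout 1 and knockout 3 lay on chromosome 6 (68000001 to 73000000) and chromosome 12 (112000001 to 117000000). The chromosome 8 window held 5 and 0 genes in these splits. The chromosome 12 window spans Igha and Ighg3 (starts 113254830 and 113356224), antibody genes that varied between libraries of the same group. Which other genes filled these windows was not tested.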
